A study of Arabidopsis thaliana and Brassica napus with 94 samples.

How the data were processed

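Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on shoots and roots of 2-week-old plants and on stems of 4-week-old plants. The 94 libraries, 90 from Arabidopsis thaliana and 4 from Brassica napus, fell into 48 groups by their labels. Of these groups, 46 held 2 libraries and 2 held 1. Per the labels' protocols, tissue was fixed with formaldehyde and paired-end libraries were sequenced on an Illumina instrument. The immunoprecipitations used either an antibody against the Flag tag of a transgenic or knock-in protein, or antibodies against the histone marks H3K4me1, H3K4me3, H3K9ac, H3K27me3 and H3K9me2. Input DNA was sequenced for 3 genotypes, with 2 libraries each.

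The submitters' processing notes name FastQC, BWA, SAMtools, GATK and MACS2 and the build TAIR10, with no versions, order or parameters. Each library had its own MACS2 peak list, so replicates were compared as separate lists and nothing was pooled. The authors deposited a fold enrichment for every peak, a linear ratio of the pileup to the background that MACS2 used; which control library served as background is not given in the sources used here. The authors also deposited, per the file layout, the −log10 of each peak's p value and q value. The lowest −log10 q differed between lists, so the threshold of the caller was not the same in every library. The fold enrichment was used to rank peaks within a list, as a percentile, and never to compare lists. Peak lists carry no read totals, so the depth of each library is unknown and no interval that needs a depth is given. A deeper library lets a caller find more peaks, so differences in peak number can come from depth as well as from binding.

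Groups and replicate numbers came from the labels. The labels do not say whether replicates came from separate plants or cultures. The p-values of tests over libraries therefore measure the spread between these libraries, which may be technical. Those of tests over genes, regions or shifted sites hold no spread between libraries. No pair of libraries held the same list: the highest share of identical intervals was 12.5% between 2 input libraries with few peaks. The Brassica napus lists use sequence names of a Brassica napus assembly, although the processing notes name TAIR10 for these libraries too. Coordinates are 1-based, in TAIR10 for Arabidopsis and in the assembly of the lists for Brassica napus.

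Peaks on chromosomes 1 to 5 were kept. Knock-in sites were peaks of knock-in replicate 1 that overlapped a peak of replicate 2 by at least 1 bp. Merged regions were unions of the overlapping peaks of the libraries compared. A region was gained between 2 genotypes when both libraries of the genotype named first and neither of the genotype named second called it, and lost in the reverse case; the 2 other ways to split the same 4 libraries gave the size that the spread between replicates reaches. Differences in peak number and in the share of knock-in sites called were tested with two-sided exact permutation tests over libraries, for the ros1-4 effect within each background. Region calls were tested with two-sided Fisher's exact tests on called and not called libraries. The share of knock-in sites in a mark was set against 1000 circular shifts of the sites along their chromosomes. Adjusted p-values are Benjamini-Hochberg values over the tests of a family, with 0.05 as the threshold.

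No genome sequence was used here. Genes were taken from a RefSeq gene table of the assembly TAIR10.1, which gives no strand, so only names and neighbourhood were taken from it. Of the H3K4me3 peaks in this check, 97.6% overlapped a protein-coding gene, against 79.5% and 76.7% with the peaks moved by 5000 and 20000 bp. A region was named for the protein-coding genes it overlapped, otherwise for those within 1 kb, otherwise by position. The design of the list tests had set a window upstream of the gene start; without strand the gene span with 1 kb on either side was used instead, for 27444 protein-coding genes. The table holds no product names, so the 10 keyword lists were matched to symbols and synonyms. A gene counted as having a peak in a list test when all libraries of the group called it. Of 12 hand-written lists, the retrotransposon list was not analysed here because its members are not among the protein-coding genes of the table, which left 21 lists and 273 tests over 13 groups.

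The regions the text names followed a rule set before the data were examined. For ROS1 these were the 10 regions called in all 8 full-length and knock-in libraries with the highest mean percentile of the fold. For each construct they were the 5 lost and 5 kept regions with the highest percentile in the full-length libraries, and for each pair of genotypes and each tissue the 10 gained and 10 lost regions with the highest percentile. Members of the fixed gene lists were named with their calls. Features chosen after their values were seen are said to be so.

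The alternatives tried were a −log10 q of at least 5, an overlap of at least 50% of the shorter interval, the same number of peaks in every library, 500 bp bins in place of merged regions, line means in place of libraries, sites called in all 6 full-length libraries, a replicate block, and leaving out each replicate. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were checked on simulated data. With no difference, the permutation test of 6 against 6 libraries passed the threshold in 6.2% of 500 draws. With a difference of 5 SD it did so in 100%. Simulated libraries, here and for the region test, were drawn independently, whereas the real ones came 2 to a line. The simulations therefore do not give the rate of false calls where libraries of a line are alike. The region test between full length and D971A recovered none of 200 planted regions and all of 2000. Its smallest p, 0.0021645 for 6 against 6 libraries, passes the adjustment only when at least 879 regions reach it, so a count of 0 from that test does not exclude a smaller set of regions. For the N-terminal deletion it recovered 2000 of 2000 planted regions with 3 false calls.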

Results

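ROS1 is the DNA glycosylase that removes 5-methylcytosine from the Arabidopsis genome, and the series title names its roles in chromatin accessibility and DNA methylation. The ChIP-seq libraries recorded where Flag-tagged ROS1 was found, what its truncated and catalytic-site forms bound, how its relatives DML2, DML3 and DME and the polymerase IV subunit NRPD1 were distributed, and how H3K9ac and H3K4me3 differed between plants with and without ROS1. Full-length ROS1 came as a transgene in the ros1-4 mutant, in 3 lines with 2 shoot libraries each, and as a knock-in at the gene itself with 2 shoot libraries. The 5 altered forms compared with it were D971A (a substitution of the catalytic aspartate), a form without the CXXC domain, and forms without 294 residues at the N terminus, 146 at the C terminus, or both. H3K9ac was profiled in Col-0 (wild type), ros1-4, gcn5 (a histone acetyltransferase mutant), hda6 (a histone deacetylase mutant) and the double mutants, and H3K4me3 in Col-0, ros1-4, sdg2-4 (a histone methyltransferase mutant) and its double mutant, with 2 libraries per genotype. Each library came as a list of peaks called by the authors. The 6 input libraries held between 6 and 64 peaks and covered 0% of the knock-in sites; lists this short do not give the share that chance would give to longer lists. A list of peaks does not show whether a mutated gene is lost, so the genotype labels of the histone libraries could not be checked.

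The ROS1 gene itself (AT2G36490, chromosome 2) served as a check of the construct labels. In 25 libraries with a Flag-tagged ROS1 transgene a peak began at 15308262, at the same base in every one of them. The 6 libraries of the C-terminal deletion began at 15309011 instead. All 6 libraries of the N-terminal deletion had a gap inside the gene; the part to the left ended at 15313206 in 5 of them and the next part began at 15314222 in 4. In the 4 libraries of the double deletion the long peaks began between 15309013 and 15309165, and a gap ran from between 15313107 and 15313205 to between 15314240 and 15314300. These edges lay close to those of both single deletions, but none was at the same base. On the right, peaks ended at 15315891 in the 6 D971A libraries, at 15315892 in 20 libraries of the deletions and of the form without the CXXC domain, and at 15316280 or 15316346 in full-length libraries. The 2 knock-in libraries had none of these edges; replicate 1 had peaks from 15307453 to 15309052 and from 15314157 to 15315442. Input libraries had no peak there. The map of peaks over the gene shows these edges. Peaks over this gene include transgene DNA, so they were not read as binding.

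**Figure D1:**
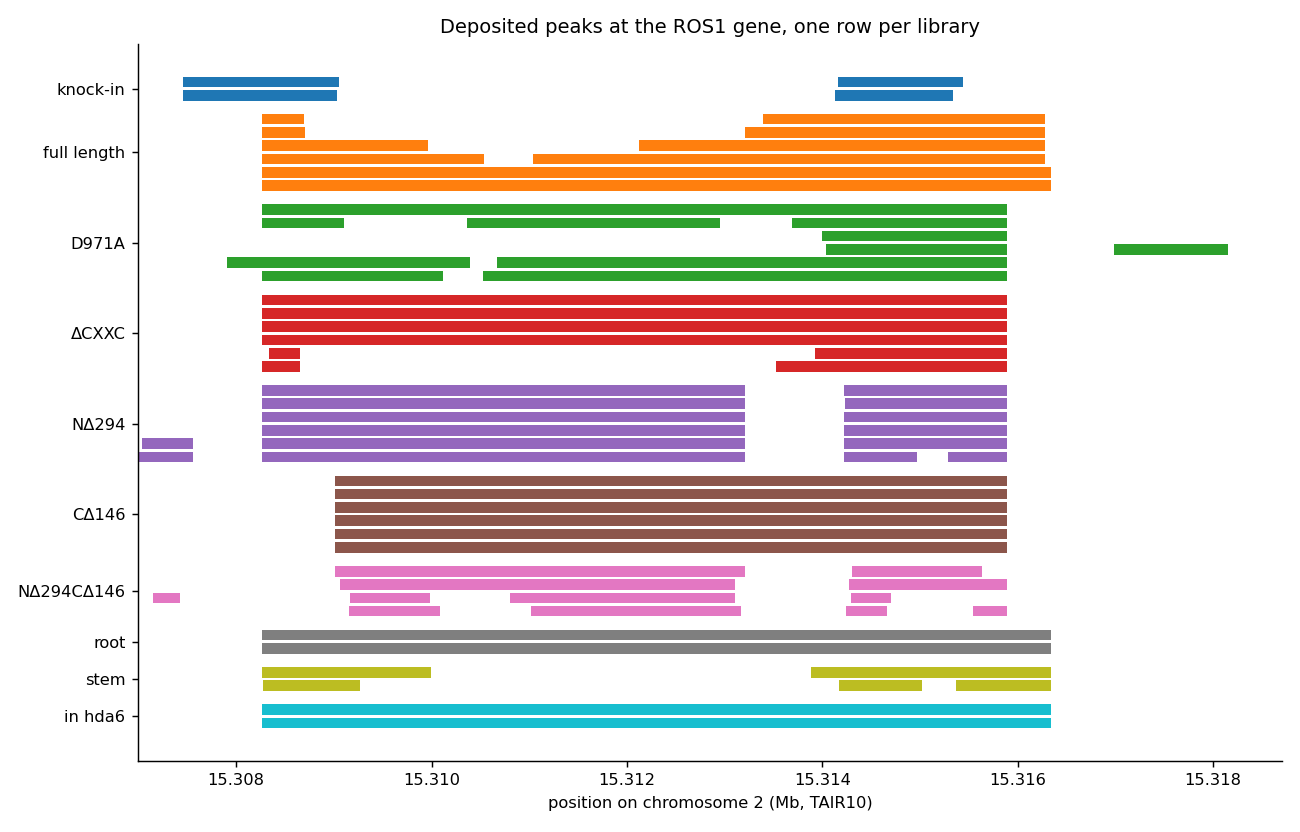
Peaks over the ROS1 gene on chromosome 2 (x axis, TAIR10 position in Mb), with the libraries below each other and each bar a deposited peak. Bars of the C-terminal deletion begin at 15309011, those of the N-terminal deletion leave a gap that ends at 15314222 in 4 libraries, and the knock-in libraries lack the edges of the transgene libraries.

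Knock-in ROS1 was called at 10333 sites that both libraries shared, which covered 15.4 Mb with a median width of 916 bp. The full-length transgene lines called 93.2% ± 2.34 of these sites (SD, n = 6). Of the 19666 merged regions of these 8 libraries, 7770 were called in all of them. The regions with the highest fold percentile lay over AT2G27080 and AT2G27090 (chromosome 2, 11564518 to 11569606), over LRX3, a cell wall extensin (chromosome 4, 7755772 to 7763498), and over EXO, a gene of cell expansion (chromosome 4, 5736230 to 5743318). They were followed by AGP1 with its neighbours, WRKY22, the region of DIC2, the region of HSPRO2, the region of TPI, AT1G17620, and the region of TCH4, a touch-induced cell wall enzyme. These regions are not specific to ROS1 as far as calls go: the 50 peaks with the highest fold in each knock-in library were all called in both nrpd1-3 libraries of NRPD1, another Flag-tagged protein, though none was among the 50 highest of NRPD1 itself. Among the fixed lists, all 16 photosynthesis genes had a knock-in peak in both libraries, against 47.3% of other genes (Fisher's exact test, adjusted p = 9.4e-05). This was not specific to ROS1: NRPD1 was called in both libraries at 11 of the 16 (68.8% against 28.8%, adjusted p = 0.00754, Fisher's exact test), and the terminal deletions below kept most of them. Of 19 defence genes, 16 had one (84.2% against 47.3%, Fisher's exact test, adjusted p = 0.0117). These included the receptor gene FLS2, the resistance genes RPM1, RPS2 and SNC1, and WRKY33, but not PR1, FRK1 or RMG1. Receptor-like proteins and kinases had one more often (57.1% against 47.2%, adjusted p = 0.0299) and MADS-box genes less often (30.6% against 47.3%, adjusted p = 0.00754, Fisher's exact tests). The tests were two-sided and ran over genes, which are not independent replicates. In the full-length lines photosynthesis genes (all 16, adjusted p = 0.00156), receptor-like genes (67.0% against 56.7%, adjusted p = 0.0193) and MADS-box genes (41.8% against 56.8%, adjusted p = 0.0175) passed in the same directions (Fisher's exact tests), while defence genes did not pass (84.2% against 56.8%, adjusted p = 0.0738) except with a −log10 q of at least 5 (adjusted p = 0.0446, Fisher's exact test). Heat shock proteins and chaperones passed there as well (74.1% against 56.7%, adjusted p = 0.0373, Fisher's exact test). Without the 1 kb flanks the full-length calls for receptor-like genes and heat shock proteins ended (adjusted p = 0.101 and 0.0878, Fisher's exact tests), and the latter also with a −log10 q of at least 5.

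Among loci reported as ROS1 targets, EPF2 (a stomatal patterning peptide), DOGL4, RLP43 and APUM9 were called in 2 of 2 knock-in and 6 of 6 full-length libraries. RMG1, a resistance gene, was called in 0 of 2 and 6 of 6. SDC and FWA, both silenced by DNA methylation in shoots, were called in none of these 8 libraries. The list as a group did not pass the test in either set. Of the stomatal lineage genes, EPF1, TMM, SPCH, MUTE and ER had a peak in all 8 libraries. Of the other genes for DNA demethylation, DME, DML3, ZDP, XRCC1 and IDM1 did. Of those for RNA-directed DNA methylation, AGO6, DMS3, SHH1 and IDN2 did, while NRPD1 was called in 0 of 2 knock-in and 5 of 6 full-length libraries. NLR genes had a knock-in peak in 9 of 13 (adjusted p = 0.324), histone genes in 14 of 20 (adjusted p = 0.13), F-box genes in 21 of 31 (adjusted p = 0.098), defensin-like genes in 2 of 7 (adjusted p = 0.628) and the single transposable element gene in none (adjusted p = 1, Fisher's exact tests). F-box genes passed with a −log10 q of at least 5 (adjusted p = 0.0313) and without the 1 kb flanks (adjusted p = 0.0105, Fisher's exact tests), and in the full-length lines without the flanks (adjusted p = 0.0230, Fisher's exact test). Heat shock proteins and chaperones passed in the knock-in without the flanks (adjusted p = 0.0454, Fisher's exact test).

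Forms of ROS1 that lacked either end had far fewer of these calls, though the amounts of protein and sequencing are not known. The full-length lines had 17890.5 ± 1669.66 peaks (SD, n = 6), the N-terminal deletion 4444 ± 930 (n = 6), the C-terminal deletion 4150.5 ± 660 (n = 6) and the double deletion 4297 ± 1845 (n = 4). Two-sided exact permutation tests gave adjusted p = 0.00361 for the N-terminal deletion, 0.00361 for the C-terminal deletion and 0.00595 for the double deletion. The share of knock-in sites called was 28.1% ± 3.04 in the N-terminal deletion, 28.5% ± 4.98 in the C-terminal deletion and 27.4% ± 10.1 in the double deletion. Each lay below the 88.6% of the lowest full-length library (exact permutation tests, adjusted p = 0.00541, 0.00541 and 0.00794). With line means as units, 3 against 3 or 3 against 2, the differences kept their size but could not pass the threshold (adjusted p = 0.125 or 0.167, exact permutation).

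**Figure D2:**
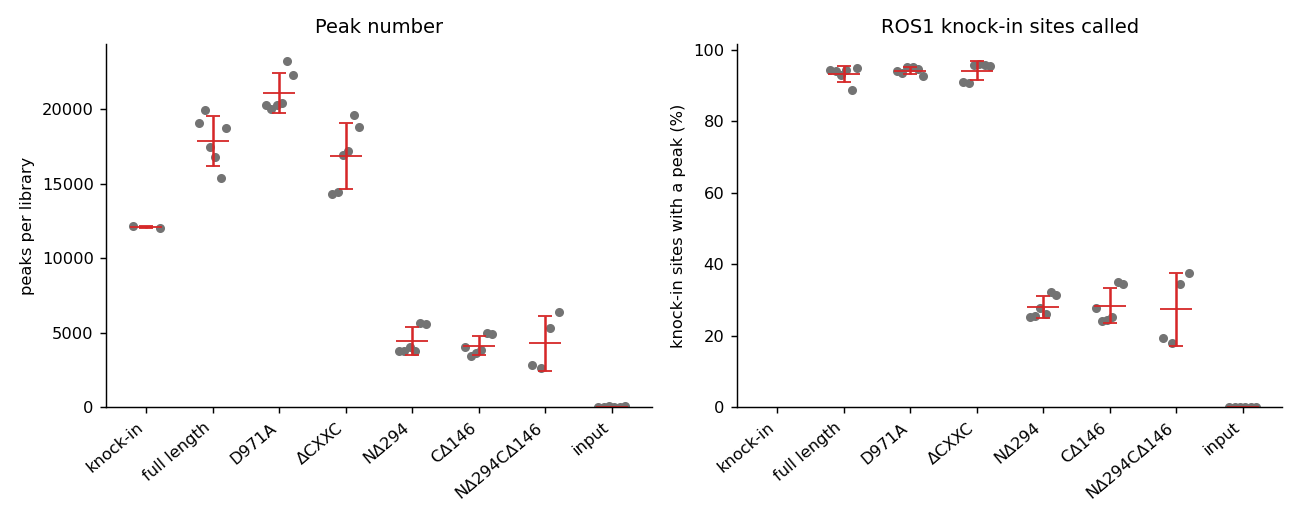
Peaks per library and the percentage of knock-in sites called (y axes) for full-length ROS1, its 5 altered forms and inputs, with knock-in libraries beside them for peak number; each point is a library and bars give the mean ± SD. The 3 terminal deletions sit between 18.01% and 37.7% of sites, below all full-length libraries, which sit between 88.6% and 94.9%.

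The loss followed the strength of the sites. In the 20% of knock-in sites with the highest fold, the N-terminal deletion called 68.4% ± 2.09, the C-terminal deletion 69.9% ± 4.67 and the double deletion 66.9% ± 11.4. In the lowest 20% the shares were 12.9% ± 3.61, 11.99% ± 3.99 and 11.7% ± 7.41, while full length called 85.6% ± 4.82 there. When every library was reduced to the same number of its best peaks, the gap narrowed: 38.5% for full length against 26.3% for the N-terminal deletion, 35.4% against 25.9% for the C-terminal deletion, and 27.2% against 20.8% for the double deletion. All 3 stayed past the threshold (exact permutation tests, adjusted p = 0.00541, 0.00541 and 0.00794).

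By region, 9666 were called in fewer libraries of the N-terminal deletion than of full length and 297 in more. The counts were 9695 and 143 for the C-terminal deletion and 7694 and 99 for the double deletion (Fisher's exact tests with adjustment). With equal peak numbers the first count of each pair fell and the second rose, to 1453 and 996, 1200 and 803, and 690 and 523. Of the regions in all 6 full-length libraries, 69.2%, 68.4% and 68.4% were called in no library of the N-terminal, C-terminal and double deletion. The strongest regions lost in the N-terminal deletion lay over FMO GS-OX1, a glucosinolate enzyme, AT2G41980, AT1G49200, XIB (a myosin) and AT5G47590 to AT5G47620. The C-terminal deletion lost the region of OCT2, that of AT2G41980, AT1G49200, AT5G47590 to AT5G47620, and AT3G22090. The double deletion lost AT4G30400, MYB117, PME5 (a pectin methylesterase), CER1 (a wax biosynthesis gene) and CYP72A11. The 3 deletions kept the same strongest regions, over AT2G27080, LRX3, EXO and AGP1. They also kept all of LHCB1.1, LHCB1.2, LHCB1.3, LHCB2.1, LHCB2.2 and LHCB3, which encode light-harvesting proteins, and ACT2, ACT7 and UBQ10, in every library. EPF2, DOGL4, RLP43 and APUM9 were called in no library of the 3 deletions.

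The D971A form had 21077 ± 1342 peaks (SD, n = 6), more than full length (exact permutation test, adjusted p = 0.00361; with line means as units it could not pass, p = 0.125), and called 94.2% ± 0.903 of the knock-in sites, which did not differ from full length (adjusted p = 0.543, exact permutation test). Its direction turned with equal peak numbers, to 88.5% against 90.9%. No region passed Fisher's exact test with adjustment, and 1894 had an unadjusted p under 0.05. Leaving out the second replicate of the unnumbered full-length line gave 1239 regions in more D971A libraries, and leaving out the second replicate of D971A line 1 gave 870. Of the regions in all 6 full-length libraries, 97.9% were called in all D971A libraries. The strongest regions absent from D971A lay over NAC071 and AT5G42170 and at 3 positions without a gene nearby, out of 20 in all. By the order of their records, the D971A libraries were deposited as a block without any full-length library. A batch and the construct therefore cannot be told apart.

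The form without the CXXC domain had 16867.5 ± 2185 peaks (SD, n = 6; adjusted p = 0.366, exact permutation test) and called 94.1% ± 2.63 of the knock-in sites (adjusted p = 0.543, exact permutation test). With equal peak numbers it called 2.89 percentage points more than full length, past the threshold (adjusted p = 0.0325, exact permutation test). No region passed Fisher's exact test with adjustment, and 180 had an unadjusted p under 0.05. Over DOGL4 or within 1 kb of it, 0 of 6 libraries of this form had a peak, against 6 of 6 of full length and 6 of 6 of D971A. All 6 had a peak just beyond that window, from 10266651 or further right, which merges with full-length peaks there, so DOGL4 is not among the regions absent from this form. Those regions numbered 5 and lay near AT2G27775 and AT3G23740, over MORF4 and ATP5, and at chromosome 2, 11357495 to 11358203.

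ROS1 sites overlapped marks of active gene starts more often than shifted sites did. H3K4me3 regions held 51.4% of knock-in sites against 25.7% after shifting, and H3K9ac regions 52.2% against 26.7%. H3K4me1, a mark of gene bodies, held 9.76% against 34.0%, and H3K9me2, the mark of silent heterochromatin, 1.07% against 13.7%. Each of these 4 differences had p = 0.001, the smallest that a permutation by 1000 circular shifts can give (adjusted p = 0.00128). H3K27me3, the Polycomb mark, held 22.3% against 20.8%, which did not pass the threshold (adjusted p = 0.0697, permutation by shifts). It passed upward with a −log10 q of at least 5 (adjusted p = 0.0101) and with sites called in all 6 full-length libraries (adjusted p = 0.00112), and downward when the overlap had to reach 50% of the shorter interval (adjusted p = 0.0371, permutation by shifts), so its direction depended on the setting. Of the sites, 58.3% lay in H3K4me3 or H3K9ac regions, 11.7% in H3K27me3 regions without either, and 26.9% in none of the 5 marks.

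**Figure D3:**
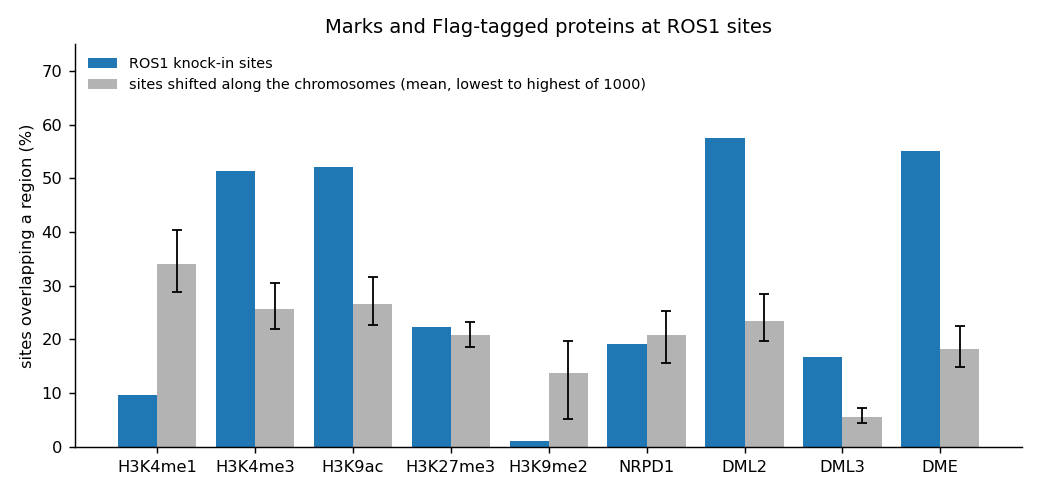
Percentage of knock-in ROS1 sites (y axis) in regions of 5 histone marks and of NRPD1, DML2, DML3 and DME, as observed and after 1000 circular shifts (mean, with the lowest and highest shift). H3K4me3 and H3K9ac hold 51.4% and 52.2% of sites, above every shift, and H3K9me2 holds 1.07%, below every shift.

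The marks separated the fixed lists in wild-type shoots. H3K27me3 covered all 21 Polycomb developmental regulators, among them AG, STM, FLC, LEC2 and WUS (adjusted p = 1.12e-08), and 12 of 14 root identity genes (adjusted p = 0.00179), but 0 of 12 housekeeping genes (adjusted p = 0.0302, Fisher's exact tests), a call that ended without the 1 kb flanks (adjusted p = 0.176). H3K4me3 covered all 68 ribosomal protein genes (adjusted p = 1.6e-10) and 2 of 21 Polycomb regulators (adjusted p = 3.18e-06, exact tests). H3K9ac covered 67 ribosomal protein genes (adjusted p = 5.6e-10), all 12 housekeeping genes (adjusted p = 0.0464) and 4 Polycomb regulators (adjusted p = 0.000271, exact tests). Cytochrome P450 genes were in H3K27me3 more often (56.0% against 35.6%) and in H3K4me3 less often (44.4% against 65.9%) than other genes (exact tests, adjusted p = 1.12e-08 and 1.25e-09). Of 14 stem cell wall genes 3 had H3K4me3 (exact test, adjusted p = 0.00680). H3K4me1 covered all 16 genes for DNA demethylation (adjusted p = 0.00371), all 18 for RNA-directed DNA methylation (adjusted p = 0.00128) and all 14 maintenance and histone modifier genes (adjusted p = 0.00926, exact tests). No list passed for H3K9me2.

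The regions of the other DNA glycosylases overlapped those of ROS1 more than shifted regions did. Of knock-in sites, 57.5% lay in DML2 regions against 23.5% after shifting, 16.7% in DML3 regions against 5.50%, and 55.0% in DME regions against 18.3% (adjusted p = 0.00128 each, permutation by shifts). In reverse, 59.0% of DML2 regions, 88.5% of DML3 regions and 82.7% of DME regions held a knock-in site. None of the 3 covered 28.2% of knock-in sites. Of the 50 peaks with the highest fold, 95% in DML2, 95.7% in DML3 and 100% in DME libraries were also called in NRPD1 libraries. The sharing of these strongest peaks was thus not separated from recovery by Flag immunoprecipitation. Over all knock-in sites, NRPD1 regions, which covered 14.1 Mb, held 19.2%. DML2 regions (15.7 Mb) held 57.5% and DME regions (14.5 Mb) 55.0%. This argues against recovery of the kind seen in NRPD1 as the only source of the DML2 and DME sharing. The DML3 share of 16.7% gives no such contrast. As in NRPD1, photosynthesis genes were covered more often than others: all 16 had a DML2 peak, 14 a DML3 peak and 15 a DME peak (Fisher's exact tests, adjusted p = 0.000407, 6.37e-10 and 2.33e-05). Both libraries of the DML2 group covered none of the 8 reported ROS1 targets (adjusted p = 0.0181; 5 of the 8 were called in 1 of the 3 DML2 libraries) and 3 of 21 Polycomb regulators (adjusted p = 0.00553) in its group (exact tests). PI and SHP1, regulators of flower and fruit development, were called in all 3 DML2 libraries. Without the 1 kb flanks the call for the reported targets ended (exact test, adjusted p = 0.0727). DME covered EPF2 in both libraries. The DML2 group had 13931 and 11048 peaks and its second line 5882. The DML3 group had 4441 and 2443 and its second line 5361. Taken singly, the DML3 libraries called 26.1% and 16.7% of knock-in sites, and the second line 40.7%. The 16.7% in DML3 regions, which both group libraries had to call, was thus limited by the shorter list. NRPD1 held 19.2% of knock-in sites against 20.9% after shifting, which did not pass the threshold (adjusted p = 0.342, permutation by shifts), while with sites called in all 6 full-length libraries the share was below the shifts (adjusted p = 0.032).

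The effect of ros1-4 on H3K9ac as a whole did not pass the test. Across the wild-type, gcn5 and hda6 backgrounds, ros1-4 libraries had 454 more peaks on average (p = 0.13, exact permutation test within backgrounds), differed by -0.543 Mb in length covered (p = 0.157, exact permutation) and called 0.881 percentage points more knock-in sites (p = 0.139, exact permutation). Without Col-0 replicate 2 the share rose by 1.34 points (p = 0.0463, exact permutation), and without gcn5 ros1-4 replicate 2 the length fell by 0.694 Mb (p = 0.037, exact permutation). The backgrounds differed in the direction of the peak number, with 689.5 more in Col-0, 1086 more in hda6 and a change of -414 in gcn5.

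Single regions changed beyond the other splits of the same libraries. H3K9ac gained 618 and lost 362 regions in ros1-4 against Col-0, and the other splits gave at most 99. With equal peak numbers the balance turned, to 2.68% gained and 3.74% lost, from 3.84% and 2.25% of the regions compared. In 500 bp bins it turned as well, to 3.75% and 6.47%. Of the regions gained in ros1-4, 44.3% were called in gcn5 and 35.3% in hda6 libraries (means over libraries). Of the lost regions, only 55.5% and 56.4% were called there. Neither genotype carries ros1-4, and the same Col-0 libraries served all 3 comparisons. Many of these changes were thus not particular to ros1-4 or not separated from the calls of the Col-0 libraries. The strongest lost region lay over MRD1 and HEI10, a meiotic crossover gene (chromosome 1, from 19963065). Others lay over AT3G44570, near AT2G17540 and TRM26, over QQS, a regulator of starch content (chromosome 3, from 12348905), and over AT2G27229, POLA2, AT1G08940 and AT5G19110. The strongest gained region lay over AT1G75945 (chromosome 1, from 28515334), followed by XTH4, CES101, ELP, AT4G39420, BBX9, AT3G18050, AT4G16957 and TIP2;2, an aquaporin. Regions gained or lost in ros1-4 lay at knock-in sites as often as other H3K9ac regions did (47.4% against 43.6%, adjusted p = 0.112, and 45.3% against 43.8%, adjusted p = 0.667, Fisher's exact tests). With sites called in all 6 full-length libraries the gained regions did so more often than others (log2 odds ratio 1.14, adjusted p = 6.63e-17, Fisher's exact test). The tests at knock-in sites, here and below, ran over regions, which are not independent replicates. They did not match changed and other regions by width or strength, and the gained and lost regions here had low median percentiles of 8.50 and 9.67.

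In the gcn5 background, ros1-4 gained 579 and lost 741 H3K9ac regions (other splits at most 57), or 3.58% and 4.59% of those compared. The same gcn5 libraries were also compared with Col-0. Of the regions gained there, 529 overlapped these losses, where independent lists would share 60.0. Of the regions lost there, 223 overlapped these gains, against 36.5. Much of the change was thus a return to the Col-0 calls, and an effect of ros1-4 was not separated from the calls of the shared gcn5 libraries. The balance turned with equal peak numbers (4.38% and 3.77%) and in 500 bp bins (6.29% and 5.27%). GCL1, PPT2, RRTF1 (an ethylene response factor) and AT5G43660 were among the strongest gained, and AT1G25211, AT4G10265 and AT2G27229 among the strongest lost. These libraries are separate from those of the Col-0 comparison. The gained regions shared 74 with those gained in Col-0 and the lost regions shared 44, where independent lists of these sizes would share 22.2 and 16.7. Regions of opposite direction shared 13 and 13, where independent lists would share 28.5 and 13.0. No test of these overlaps was run. All counts given for independent lists take every region as equally likely to change. The regions gained and lost here had low median percentiles of 10.6 and 10.5, so unrelated lists of weak regions may share more than these counts. The gained regions lay at knock-in sites in 52.5% against 44.8% of others (adjusted p = 0.000585) and the lost ones in 35.5% against 45.6% (adjusted p = 1.49e-07, Fisher's exact tests). In the hda6 background, ros1-4 gained 654 regions (3.99% of 16386) and lost 1.73% (other splits at most 45 regions), and with equal peak numbers the balance turned, to 1.83% gained and 3.36% lost, and in 500 bp bins to 2.72% and 6.81%. The same hda6 libraries were also compared with Col-0. Most regions lost in hda6 ros1-4 overlapped regions gained in that comparison, where independent lists would share 18.7. Many regions gained in hda6 ros1-4 overlapped regions lost there, against 18.1. An effect of ros1-4 was thus not separated from the calls of the shared hda6 libraries. Of the regions lost in hda6 ros1-4, 25.1% lay in H3K9me2, and the strongest included AT3G45093, AT3G43574, NAC093, AT3G44570 and AT3G30820. SPL8 and AIR3 were among the gained. With the ros1-4 regions of the Col-0 background they shared 41 gained and 15 lost, against 25.1 and 6.36 for independent lists. They also shared 19 and 39 of opposite direction, against 10.9 and 14.7, so the sharing was not specific to the same direction. Between the gcn5 and hda6 backgrounds, 13 gained and 7 lost regions were shared, against 23.4 and 13.0 for independent lists. Regions lost in gcn5 and gained in hda6 shared 60 against 30.0, and those gained in gcn5 and lost in hda6 shared 10 against 10.1. Lost regions lay at knock-in sites less often than others (24.7% against 42.5%, adjusted p = 3.07e-09, Fisher's exact test).

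The deacetylase mutant hda6 gained 1067 H3K9ac regions against Col-0 and lost 447 (other splits at most 90). Of those gained, 16.3% lay in H3K9me2 regions, against 0.418% of the regions called in all 4 libraries. AT5G15360, AT4G07965, AT5G26270, AT5G36900, AT1G58025, AT4G29200 and AT3G45093 were among the strongest gained, with 3 of the 10 away from any gene. Gained regions lay at knock-in sites in 25.9%, against 43.8% of others (adjusted p = 2.23e-30, Fisher's exact test). Their median percentile was 14.9, and width and strength were not matched, so this contrast may reflect either. AIR3, NQR and AT5G44380 were among those lost. The acetyltransferase mutant gcn5 gained 1356 and lost 1056 regions (other splits at most 39), a balance that turned with equal peak numbers (1154 and 1245) and in 500 bp bins (3353 and 3781 bins). It gained regions over BCAT-2, MYBL2 (a repressor of anthocyanin synthesis), NAC6, Rap2.6L, MSS1 and RIBA2, and near ERF9. It lost regions over LHY, a clock gene, AT3G56300, AT1G47820 and EMB2758, and those of HEI10 and AT2G17540. Lost regions lay at knock-in sites in 29.6%, against 45.2% of others (adjusted p = 8.07e-23, Fisher's exact test). Without read totals, the counts of gcn5 and hda6 do not show whether H3K9ac as a whole rose or fell. AT1G75945 was also gained here and the same Col-0 libraries served both comparisons, so these repeats are not independent.

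**Figure D4:**
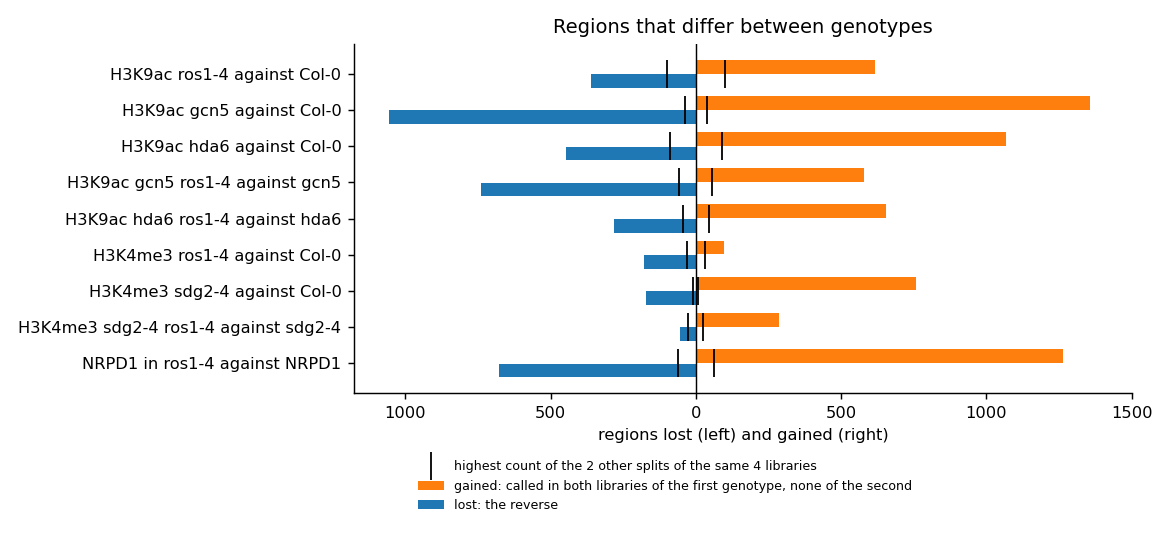
Regions gained (right) and lost (left; x axis, number of merged regions) in each comparison of 2 genotypes with 2 libraries each, with marks at the highest count that another split of the same 4 libraries gave. NRPD1 in ros1-4 gained 1262 and lost 677, and no other split gave more than 99 in any comparison.

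H3K4me3 peaks were narrower in both libraries of ros1-4 in each background, which the tests could not call. The length covered was 10.6 Mb against 12.4 Mb in Col-0 and 13.2 against 13.9 in sdg2-4, lower in all ros1-4 libraries of each background (a mean difference of -1.19 Mb, p = 0.0556, exact permutation test, the smallest that 36 arrangements allow). The peak number was 385 higher on average (p = 0.0556, exact permutation). The share of knock-in sites differed by -0.619 percentage points (p = 0.389, exact permutation). The median peak width was 768.5 ± 9.19 bp in Col-0 and 658 ± 4.24 bp in ros1-4, and 859 ± 2.83 bp in sdg2-4 and 791 ± 9.90 bp in the double mutant (SD, n = 2 each). Against Col-0, ros1-4 gained 98 and lost 177 regions (other splits at most 30), or 0.670% and 1.21% of those compared, and 0.202% and 8.87% of 500 bp bins. In the sdg2-4 libraries, 77.0% of the gained and 68.6% of the lost regions were called. Many of the gains were thus not particular to ros1-4. Lost regions lay over QQS, AT2G27229, BGLU18 (a glucosidase of abscisic acid release), AT3G44570, SCPL34 and AT5G24210, and near AT2G17540 and TRM26. Gained regions lay over AT1G75945, AT1G25211, EDA6, RBL7 and CYP78A9. Of the lost regions 63.3% lay at knock-in sites, against 41.5% of others (adjusted p = 2.52e-08, Fisher's exact test); with sites called in all 6 full-length libraries this call was lost (adjusted p = 0.18).

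The sdg2-4 mutant gained 757 and lost 172 H3K4me3 regions against Col-0 (other splits at most 9). These were 4.98% and 1.13% of the regions compared, and 2.87% and 2.15% with equal peak numbers. Peak lists carry no read totals, so these counts do not show whether H3K4me3 as a whole rose or fell in sdg2-4. Lost regions lay over AT2G32150, AT2G30600, LRX2, QQS and WRKY26, and 75.6% of them lay at knock-in sites against 42.2% of others (adjusted p = 6.46e-18, Fisher's exact test). JMJD5, CYP78A9 and HCAR were among the gained. Adding ros1-4 to sdg2-4 gained 287 and lost 54 (other splits at most 26). The balance turned with equal peak numbers, to 0.573% gained and 1.37% lost, from 1.86% and 0.350%, and in 500 bp bins to 1.43% and 3.94%. HIS1-3 (a stress-induced linker histone), MAF5 (a flowering repressor) and PRR9 (a clock gene) were gained, and AT2G35460, AT2G27229, AT2G17540, RLP19 and MYB48 were among the lost.

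NRPD1 calls differed between plants with and without ROS1. In nrpd1-3 ros1-4 against nrpd1-3, NRPD1-Flag gained 1262 regions and lost 677 (other splits at most 63), with 10983.5 ± 88.4 against 10345 ± 89.1 peaks (SD, n = 2 each). The gained regions had a median percentile of 47.4 and the lost regions of 13.7. The highest lay over AT1G63340 and AT1G63350 (chromosome 1, from 23493508), AT1G49570 (a peroxidase gene), NTL8 (a membrane-bound transcription factor), LBD33, NUDT9, AT5G11370, AT3G19070 and PRK6 (a pollen receptor kinase). EPF2 and DOGL4 were called in 0 of 2 libraries with ROS1 and 2 of 2 without. LURP1 and CKX4 were among those lost. Of the gained regions 42.6% lay in H3K27me3 and 1.58% in H3K9me2, while 48.0% of those lost lay in H3K9me2. Regions called in all 4 libraries lay in H3K27me3 in 20.9% and in H3K9me2 in 25.3%. At knock-in sites lay 30.7% of the gained against 24.6% of others (adjusted p = 1e-05) and 8.27% of the lost against 26.5% (adjusted p = 2.23e-30, Fisher's exact tests). For the gained regions this ended with a −log10 q of at least 5 (adjusted p = 0.0718, Fisher's exact test).

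ROS1 was compared between shoot, root and stem, with 2 libraries each for root and stem. Of root peaks 81.6% ± 3.67 were called in shoot libraries (12 pairs of libraries), against 92.2% ± 0.643 between root replicates. Of shoot peaks 72.4% ± 3.83 were called in root, against 88.3% ± 6.68 between shoot lines. The shares with equal peak numbers were 71.02% and 80.6%. Root gained 1005 regions called in none of the 6 shoot libraries and lost 1581; 47.8% of the gained lay in shoot H3K27me3, against 32.1% of the shared regions. Gained regions lay over PHT1;1, a phosphate transporter, HEC3, the region of THA2 and PPCK2, TET6 and PSBQ-2. Of the root identity genes, PHT1;1 and RHD6, a root hair factor, were called in both root and no full-length shoot library, and WER in 2 of 2 and 1 of 6. As a list, root identity genes did not pass in root (11 of 14, 78.6% against 58.8%, adjusted p = 0.335, Fisher's exact test), and PLT1, PLT2 and IRT1 were called in no root library. Lost regions lay over the cluster of RBCS1B, RBCS2B and RBCS3B (chromosome 5, 15374901 to 15383558), DFL2, ZFP8, PKS4 and IAMT1. The LHCB genes were called in 0 of 2 root libraries and 6 of 6 shoot libraries, while LHCA1, LHCA2, LHCA4, RBCS1A, PSAD1 and RCA were called in both root libraries. The terminal deletions also kept the LHCB genes in every shoot library, so this difference was not shown to be specific to ROS1 binding. As a list, photosynthesis genes in root did not pass the test (37.5% against 58.9%, adjusted p = 0.286, Fisher's exact test).

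The names of the peaks in the stem lists contain the word atac, although the labels give Flag ChIP-seq. It is therefore not settled that the stem lists record ROS1 rather than open chromatin, and what follows is given under their labels. In stem, 802 regions were gained and 723 lost against shoot. The cell wall genes CESA7, CESA8 and LAC17 and their regulator NST3 were called in both stem libraries and in none of the 6 shoot libraries. LAC4 was called in 1 of 2 stem and 5 of 6 shoot libraries, and VND6 and XCP1 in no stem library. As a list, 11 of 14 cell wall genes had a stem peak, which did not pass (78.6% against 58.4%, adjusted p = 0.335, Fisher's exact test). STOMAGEN, which promotes stomata, TT8 (a flavonoid regulator), TPS10 and BNQ2 were among those lost. The gained regions with the highest percentile were AT2G01023, AT2G01008 and AT2G08986 and 5 positions without genes nearby. Of stem peaks 83.4% ± 4.90 were called in shoot libraries and 73.4% ± 8.94 of shoot peaks in stem. The 2 stem libraries differed, at 84.2% and 73.6% of knock-in sites. The differences in shares and regions between tissues were not tested.

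In the hda6 background, full-length ROS1 called 92.6% and 83.5% of knock-in sites in its 2 libraries. Both hda6 libraries called 193 regions that none of the 6 full-length libraries called, and neither called 245 that all 6 did. For comparison, each full-length line was set against the 4 libraries of the other lines, which gave 69 to 189 gained and 58 to 108 lost. Set against the same 4 libraries, hda6 gave 220 to 347 gained and 306 to 809 lost, above the counts between lines in each case. With a −log10 q of at least 5 the gained regions numbered 114. Without hda6 replicate 1, 396 were gained and 2034 lost, and without replicate 2 the counts were 549 and 268. Gained regions lay over AT5G55580, AT5G26270, AT2G13770, AT2G10975 and BCAT-2, and lost ones over SHV3, AT2G24020 and ROS3. AT5G26270 also gained H3K9ac in hda6.

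The ChIP protocols numbered 3 (aChIP, eChIP and rChIP). The aChIP libraries had 15392 and 18717 peaks and called 88.6% and 94.9% of knock-in sites. The peak names of the eChIP lists mention flowers, although their labels give shoots, so protocol and tissue are not separated there. The eChIP libraries had 4536 and 46 peaks (5.88% and 0.0387% of sites) and the rChIP libraries 83 and 86 (0.300% and 0.435%). The ROS1 gene was called in every library of all 3. TMM, of the stomatal list, was the 1 list member besides ROS1 with an rChIP call, in 1 of 2 libraries.

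The Brassica napus libraries carried Flag on the ROS1 copy labelled A05 or C04. The A05 protein had 71611 and 71175 peaks and the C04 protein 45492 and 45503. Of C04 peaks 82.8% ± 1.21 were called in A05 libraries (4 pairs), against 77.0% ± 2.08 between C04 replicates. Of A05 peaks 51.9% ± 1.26 were called in C04, against 83.7% ± 3.23 between A05 replicates. The A05 lists were longer, which by itself lowers the share of A05 peaks in C04 and raises the reverse share. Equal peak numbers were not tried for these libraries, so the shares do not show a difference in binding. Of the A05 peaks 46.3% and 46.7% lay on the A subgenome, and of the C04 peaks 44.9% and 45.2%. The peak with the highest fold was at A05, 37676844 to 37679462, for A05 replicate 1 and at C07, 50856437 to 50865232, for C04 replicate 1, and both recurred in the second replicates. Whether these peaks are transgene DNA was not established, so they were not read as binding. No gene names were used for this genome.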

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

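All counts over other splits and the tests of the deletions, of the chromosomes and of NRPD1 with H3K9ac were chosen only after the results had been seen; the tests of weak peaks in hda6 and of the D971A regions were set before their values were computed.

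The first replicate of the unnumbered full-length line stood apart in the share of knock-in sites, at 88.6%, where the nearest library had 93.0%. Dixon's rule was applied to 18 sets and measures and marks about 1 in 20 groups by chance alone. The lowest −log10 q in this list was 5.06, against 2.00 to 2.05 in the other 5 lists, so its peaks passed a stricter threshold. With a −log10 q of at least 5 in all lists its share was 92.6% and the nearest 94.6%. Chance and the threshold both stay open. Without that library the difference of the form without the CXXC domain was -0.00839 percentage points (adjusted p = 0.996, exact permutation test).

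In a pair of measures ros1-4 libraries lay above all others in a background and below all others in another. The share of knock-in sites in H3K4me3 differed by -2.042 percentage points in Col-0 and 0.803 in sdg2-4. The H3K9ac peak number differed by 689.5 in Col-0, -414 in gcn5 and 1086 in hda6. The H3K9ac length covered also differed in sign, by -0.662 Mb in Col-0, 0.273 in gcn5 and -1.24 in hda6, with overlapping libraries in Col-0 and gcn5. These differences between backgrounds were not tested.

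Regions called in fewer or in more libraries of a construct were set against 100 splits of the same libraries, the real split included. For the N-terminal, C-terminal and double deletion the real splits gave 9963, 9838 and 7793 regions and the highest other split 0, so 1, 1 and 1 of the splits reached the real count. For the N-terminal deletion the adjusted test calls nothing unless 788 regions reach its smallest p, so a 0 in other splits says little. Without adjustment the real counts were 9963, 9838 and 10079 and the highest other splits 1109, 1139 and 2086, which excludes a random assignment of libraries. Splits of whole lines number 10, too few for a share under 0.05; the highest other gave 69, 39 and 1296. For D971A and for the form without the CXXC domain the real count was 0 and the highest other 0; every split reaches a count of 0 (100 and 100 of the splits), so this decides nothing about chance. Without adjustment the counts were 1894 for D971A (highest other 602) and 180 for the form without the CXXC domain, which 3 of 100 splits reached (highest 226). Among the 10 splits of whole lines, too few to decide, the highest others were 52 and 238. A loss of weak regions alone may explain the deletions only if strong regions stay. Of the 94 full-length regions at or above the 99th percentile, 34.0%, 24.5% and 16.0% were called in no library of the N-terminal, C-terminal and double deletion, so weak regions alone do not account for this loss. For the knock-in sites the test went the other way. Of the 122 sites at or above the 99th percentile in the knock-in, 0% were called in no library of a deletion. This 0% cannot decide, because any Flag immunoprecipitation may recover the strongest knock-in peaks. The 50 highest of each knock-in library were all called in both NRPD1 libraries. Of the 2067 knock-in sites with the highest fold, full length called 98.7% and the deletions, in the same order, 68.4%, 69.9% and 66.9%. The deletions called still smaller shares of weaker sites, so missed weak sites may explain part of the loss, which was not limited to them. Lower amounts of protein or of sequencing could also lower the number of calls, and the lists give no measure of either.

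The regions that the deletions kept could be background of the method. None of them overlapped an input peak (0% in each deletion), so pile-up strong enough to be called in input does not account for them. The input lists held at most 64 peaks, and weaker pile-up stays open. NRPD1, another Flag-tagged protein, was called in both libraries at 43.6%, 47.3% and 49.4% of the kept regions and at 15.7%, 15.2% and 15.5% of the lost regions, a ratio of 2.78 at the lowest. This is in line with regions that any Flag immunoprecipitation may recover. Kept regions also lay in H3K9ac more often (96.3% against 51.0% in the N-terminal deletion), and a library with Flag antibody on untagged plants was not used here, so open chromatin and true residual binding were not told apart.

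H3K9ac regions gained in hda6 within H3K9me2 were often lost again in hda6 ros1-4, and the share lost differed between chromosomes. Of 169 such regions 69 were lost, with 37.9%, 60%, 66.7%, 10.7% and 17.1% on chromosomes 1 to 5 (p = 0.0001, permutation, the smallest possible). Segments inherited from the parent without hda6 might give such blocks, but neighbours shared their fate in 61.0% against 60.8% after shuffling (p = 0.511, permutation), which cannot tell. Lost regions were weaker in hda6, with a median percentile 42.1 lower (a difference of -42.1), which is in line with weak peaks being missed. Within 5 classes of the percentile the chromosomes still differed (p = 0.0001, permutation, the smallest possible), so weak peaks do not account for the difference between chromosomes.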

How the results depend on the processing

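The alternatives were fixed before the data were examined, except the gene span without flanks, the added line 2 of DML2 and DML3, and leaving out each root, stem and hda6 replicate, which were chosen after seeing the data. A window from 1 kb upstream to 500 bp downstream of the gene start had also been planned and was not run, because the gene table has no strand. Of 580 main alternatives 497 left the result the same, 10 made it weaker, 8 stronger, 56 moved its value and 9 reversed its direction. Where a result changed, the cause was not tested.

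With line means as units the peak numbers differed from full length by 3186.5 for D971A, -13446.3 for the N-terminal, -13740 for the C-terminal and -13593.5 for the double deletion, and the shares of sites by -65.1, -64.7 and -65.8 points for the 3 deletions. None of these can pass with so few lines (adjusted p = 0.125 and 0.167, exact permutation tests). With equal peak numbers the share of sites differed by -2.39 for D971A (reversed) and 2.89 for the form without the CXXC domain (now past the threshold). With sites called in all 6 full-length libraries it differed by -0.768 and -6.02; full length is 100% there by definition, so these signs were fixed and show nothing.

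Counts of regions were compared as counts, and their values are given here in percent of the regions or bins compared, a scale chosen after seeing the data. Regions called in fewer and more libraries were, with equal peak numbers, 21.1% and 14.4% for the N-terminal deletion, 19.7% and 13.2% for the C-terminal deletion and 14.2% and 10.8% for the double deletion. In 500 bp bins they were 46.6% and 3.39%, 44.6% and 2.61%, and 34.3% and 1.64%. With a −log10 q of at least 5, those with more calls were 0.566% for the C-terminal and 0.353% for the double deletion.

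Leaving out each library in turn gave 2686.8 to 3597.8 for the peak number of D971A, -1568.7 to -505.9 for the form without the CXXC domain, -13946 to -13035 for the N-terminal, -14239.7 to -13328.7 for the C-terminal and -14286.2 to -13033.2 for the double deletion. The shares of sites ran from 0.0335 to 1.97, from -0.00839 to 1.61, from -66.0 to -64.6, from -66.0 to -63.9 and from -69.3 to -62.7. For D971A 0% to 0.104% of regions had fewer calls and 0% to 6.10% more, with 21 and 1239 regions without the second replicate of the unnumbered full-length line and 21 and 870 without the second replicate of D971A line 1. The N-terminal deletion had 53.3% to 58.0% fewer and 1.66% to 2.14% more, the C-terminal 55.4% to 60.1% and 0.828% to 1.16%, and the double 43.0% to 48.9% and 0.552% to 0.921%.

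For H3K9ac the ros1-4 effect ran from 304 to 603 peaks, from -0.695 to -0.391 Mb and from 0.423 to 1.34 points of sites. Without gcn5 ros1-4 replicate 2 it was -0.694 Mb (p = 0.037, exact permutation), and without Col-0 replicate 2 it was 1.34 points (p = 0.0463, exact permutation). With an overlap of at least 50% of the shorter interval the share of sites was reversed, at -0.0668. For H3K4me3 the ranges were 310.5 to 459 peaks, -1.26 to -1.11 Mb and -0.869 to -0.404 points.

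The labels pair samples across groups only by a replicate number. Deviations of equal numbers correlated at -0.0988 to 0.0876, with 0 pairs above 0.1. Batches of lines were not tested. In each terminal deletion the unnumbered line had the most peaks, which was not so for full length, so a batch shared by lines stays open. A replicate block changed 0 of 16 calls, with a difference of 3186.5 peaks for D971A (adjusted p = 0.00833, exact permutation test).

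Gained and lost regions with equal peak numbers were 2.68% and 3.74% for H3K9ac in ros1-4, 1.83% and 3.36% in hda6 ros1-4, 2.87% and 2.15% for H3K4me3 in sdg2-4, and 0.573% and 1.37% in sdg2-4 ros1-4. In 500 bp bins they were 3.75% and 6.47% for H3K9ac in ros1-4, 9.75% and 11.0% in gcn5, 9.93% and 2.67% in hda6, 6.29% and 5.27% in gcn5 ros1-4, with 6.81% lost in hda6 ros1-4. For H3K4me3 they were 0.202% and 8.87% in ros1-4, 10.4% and 3.53% in sdg2-4, with 3.94% lost in sdg2-4 ros1-4, and for NRPD1 9.43% and 6.21%. The balance of gained and lost turned in 5 of 9 comparisons with equal peak numbers and in 5 of 9 in bins: H3K9ac in ros1-4, gcn5, gcn5 ros1-4 and hda6 ros1-4, and H3K4me3 in sdg2-4 ros1-4. A −log10 q of at least 5 removed no peak from these histone lists, so it tests nothing there.

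The log2 odds of changed regions at ROS1 sites with a −log10 q of at least 5 were 0.195 for H3K9ac gained in gcn5 (now past), 0.00109 for lost in hda6 (reversed), -0.118 for gained in hda6 ros1-4 (no longer past) and 0.210 for NRPD1 gained (no longer past, adjusted p = 0.0718, Fisher's exact test). With sites called in all 6 full-length libraries they were 1.14 for H3K9ac gained in ros1-4 (now past), 0.376 for lost in hda6 (reversed), 0.365 for H3K4me3 lost in ros1-4 (no longer past) and 0.105 for lost in sdg2-4 ros1-4 (reversed).

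Without flanks 4 lists passed in stem and 3 in NRPD1, and ribosomal protein genes in H3K4me1 were reversed (log2 odds -0.596). The log2 ratio of H3K27me3 at ROS1 sites was 0.143 with a −log10 q of at least 5 (now past, adjusted p = 0.0101), -0.128 with 50% overlap (reversed and past, adjusted p = 0.0371) and 0.215 with full-length sites (now past, adjusted p = 0.00112), and that of NRPD1 -0.257 with full-length sites (now past, adjusted p = 0.032, permutation by shifts).

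With equal peak numbers 71.02% of root peaks were in shoot and 80.6% of shoot peaks in root. Leaving out a root or stem replicate gave 81.5% to 81.7% for root in shoot, 72.3% to 72.5% for shoot in root, 81.6% to 85.2% for stem in shoot and 65.5% to 81.4% for shoot in stem. ROS1 in hda6 gained 114 regions with a −log10 q of at least 5, and 396 and 549 without its first and second replicate, with 2034 and 268 lost. The rChIP libraries called 0.492% of sites with a −log10 q of at least 5. For Brassica napus, A05 in C04 was 47.7% and 50.2%, and C04 in A05 84.2% and 80.1%, with a −log10 q of at least 5 and with 50% overlap.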

Other observations

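The tests of NRPD1 with H3K9ac were chosen only after the result was seen, and so were the list genes named for D971A.

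In all 6 D971A libraries 705 regions were called that no full-length library called, against 20 in the reverse case and at most 9 in 99 other splits of the same libraries. Together these are 725, against at most 10 in other splits of whole lines, which number 10 in all and are too few for a share under 0.05. The strongest lay over RIC7, SRS4, AT1G09510, LCR62 and RBL1, AT5G03590, AT2G21920 and MYB79. Of these regions 46.5% lay in H3K27me3, against 30.2% of those called in all 12 libraries, and 10.4% against 66.3% lay in H3K9ac. Among list genes, IRT1 (an iron transporter) and NST3 were called in 6 of 6 D971A and 0 of 6 full-length libraries. The flowering gene FT was called in 6 and 1, BP in 6 and 2, SUVH2 in 6 and 1, and PR1 in 6 and 1.

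The D971A libraries had more peaks, so weak regions may have been called more often. The median percentile of these regions was 26.0, between the limits set for and against this reading, so the test cannot tell. Retention of an inactive enzyme at methylated heterochromatin would raise the share in H3K9me2. That share was 0.567% against 1.21%, a ratio of 0.468, so no such rise was seen. Both shares are small, their difference was not tested, and methylated DNA outside H3K9me2 was not examined, so this does not exclude retention. The D971A libraries were also deposited apart from every full-length library, and splits of these libraries cannot separate such a batch from the construct.

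H3K9ac regions lost in ros1-4 overlapped NRPD1 gains more often than other H3K9ac regions did. Of the 362 lost, 19 (5.25%) overlapped a region where NRPD1 was newly called in ros1-4, against 174 of 14907 others (1.17%, p = 1.7e-07, two-sided Fisher's exact test). The lost regions lay in H3K27me3 more often (27.3% against 6.67%), where NRPD1 gains also lie. With the loss shuffled within and outside H3K27me3 the mean overlap was 5.82 (p = 0.0001, permutation, the smallest possible), so H3K27me3 alone does not account for it. Outside H3K27me3 the shares were 5.32% and 1.06% (p = 1.94e-06, Fisher's exact test), and inside it 5.05% and 2.61% (p = 0.192, Fisher's exact test). Of the 618 gained, 3 did (p = 0.0943, Fisher's exact test). The 19 included AT2G17540 with TRM26, AT2G27229, AT1G08940, AT2G04080, AT3G56210 and AIR3. The region of AT2G17540 was also lost in gcn5 and that of AIR3 in hda6, neither of which carries ros1-4. Of the 362 lost, only 55.5% were called in gcn5 and 56.4% in hda6 libraries (means over libraries). Many of these losses were thus not particular to ros1-4, and the overlap was not tested without them. The NRPD1 and H3K9ac libraries were separate, but a changed segment of the ros1-4 genome could alter both.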
